A study of Mus musculus with 2 samples.

How the data were processed

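Total RNA from mouse haematopoietic stem cells was hybridised to Affymetrix expression arrays, 1 array for mice lacking Wip1 and 1 for wild-type mice. Wip1 is the phosphatase encoded by Ppm1d, known as a negative regulator of p53 and of DNA damage kinases. Both samples came from animals of 3 months, per the labels. How the stem cells were sorted, the number of animals behind each sample and their sex are not given in the sources used here.

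The authors deposited 1 summarised intensity per probe set and array, on a linear scale, for 45037 probe sets. MAS5 is the only program named in the submitters' processing notes, without a version. The deposited intensity values ran from 3.79 to 23137 on the knockout array and from 3.54 to 23180 on the wild-type array, with medians of 25.9 and 25.2. A total of 2535 probe sets (5.63%) held exactly the same value on both arrays, which signals computed separately for each array would seldom give. The method that made the numbers is therefore not settled, and neither is its effect on small differences. No detection call, background or scanner value was used here, and neither array has a replicate.

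Probe sets were named through the platform's annotation, in which 34945 probe sets had 1 gene, 932 had several genes and 9160 were not listed. Of those with 1 gene, 34741 matched a gene identifier of the reference gene table (assembly GRCm38.p6), which was used for symbols and for gene order only. Probe sets with several genes or none were kept out of the gene comparison. The annotation left 18193 genes.

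The following choices were made before the data were examined. Deposited intensities were converted to log2 values, and the arrays were centred so that the median log2 difference over detected gene probe sets was 0, which removed a shift of -0.01. Each gene was represented by the probe set with the highest mean of the 2 arrays. The floor was each array's median over all probe sets, and a gene was called detected when at least 1 array lay above it, which kept 11440 genes. Values under the floor were set to it, so a difference against such a value is a lower bound. As a check of the floor, 15 of 48 genes specific to other tissues (31.2%) lay above it, against 62.9% of all genes, and 2 of the 48 lay above the 75th percentile. Being above the floor therefore does not by itself show that a gene was expressed.

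With 1 array per genotype no test across arrays can be made, and no p-value is given. The arrays' number limits the precision. The only error in the file is the disagreement between probe sets of one gene: over 5084 genes with at least 2 detected probe sets, the SD of the log2 difference attributable to a single probe set was 0.20. This SD holds neither animal-to-animal nor array-to-array variation. Differences are given as log2 knockout minus wild type, and a difference of at least 2-fold was the fixed size at which genes were counted. A total of 28 gene lists were fixed in advance. For each, the median difference of its detected members was placed among 10000 random lists of the same size, drawn from 20 bins of genes with matching mean intensity, and a list was said to stand apart when it lay outside their central 95%. About 1.4 of 28 lists would do so by chance, and more if members of a list vary together, which random lists do not mimic.

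The genes named were Ppm1d and Cdkn1a, the 10 genes with the largest difference each way among bright genes (above the 75th percentile) whose detected probe sets all differed in the same direction and whose symbol is not a clone or model name, the 5 largest each way among such genes with at least 2 detected probe sets, each past 2-fold, and the 3 members of each list with the largest difference. With every detected probe set required to pass, Il7r and Dntt met the rule on several probe sets among higher genes, and Nupr1 and Lrmda among lower genes. Timp3, H2-Aa, H2-Ab1 and Satb1 were among genes with several probe sets past 2-fold and another that was not, and did not count under it. One further gene fixed by name was not analysed here. Other genes named in the text were chosen after their values were seen.

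The procedure was tested on simulated arrays made from the real intensities with 200 changed genes, all drawn from bright genes. Recovery of changes in dim genes, where the floor can shrink a difference, was therefore not tested. The noise of the simulated arrays was assumed, not measured. The procedure placed 96.0% of genes changed by 1.5 on the log2 scale and 100% of those changed by 2.5 past 2-fold in the right direction, and 0 of 11149 unchanged genes. Of 100 lists of unchanged genes, 4 lay outside the central 95%, and the list of 30 shifted genes lay at the 100th percentile. The results for unchanged genes follow from the assumed noise and do not show how often genes of real arrays would pass. Alternatives covered the centring, quantile and loess normalization, the floor, an added offset, the probe set chosen per gene, the fold size and the matching of the random lists. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.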

Results

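Gene expression was profiled in haematopoietic stem cells, the bone marrow cells that give rise to all blood lineages, from Wip1 knockout and wild-type mice. There was 1 array per genotype. The comparison shows which transcripts differed between these 2 samples, and it cannot separate genotype from differences between any 2 stem cell preparations. Across 11440 detected genes the log2 intensities of the arrays correlated with Pearson's r = 0.987 and Spearman's rho = 0.986, where genes are not independent replicates. The SD of the log2 difference over these genes was 0.28, against an SD of 0.20 between probe sets of one gene.

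The targeted gene, Ppm1d, was measured by 2 probe sets, and both differed by less than the SD between probe sets. Their intensities were 160 and 59.0 in the knockout against 167 and 55.6 in the wild type, with log2 differences of -0.05 and 0.10. Where these probe sets lie relative to the deleted part of the gene is not given in the sources used here, so they may check nothing about the genotype label. Transcripts that depend on sex also differed between the samples. Xist, the RNA that silences an X chromosome, was lower in the knockout in each of its 3 probe sets (log2 differences of -0.86, -0.58 and -0.71) and bright in both samples, with intensities of 3778 and 6228 in its brightest probe set. The Y-linked Eif2s3y was 4.72-fold higher in the knockout (149 against 31.8), by the only one of its probe sets that was detected. Kdm5d and Uty, also Y-linked, were under the floor in the wild type and higher by at least 1.38 and 0.23 on the log2 scale in the knockout. The gene list comparisons are between samples that differ in these transcripts.

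In all, 52 genes were at least 2-fold higher and 24 at least 2-fold lower in the knockout, together 0.66% of detected genes. Gdpd3, a lysophospholipase D gene, had an intensity of 1218 in the wild type and lay under the floor in the knockout, at least 46.6-fold lower by its only probe set. Other lower genes were Timp3, an inhibitor of metalloproteinases (-2.05 on the log2 scale), the aspartic protease gene Ctse (-1.95), the stress-response gene Nupr1 (-1.62), Pik3ap1, a PI3-kinase adaptor of B cells (-1.53), the retinaldehyde dehydrogenase gene Aldh1a1 (-1.36) and Vasn (-1.22). The immunoglobulin kappa variable genes Igkv15-103 and Igkv8-30 were also lower (-1.74 and -1.36), and probe sets of such genes can share sequence with related segments. Cuedc1 was lower by its brightest probe set (-1.59), with -0.40 in another probe set and a bound of -0.13 in the one that was under the floor in the knockout. Lrmda was past 2-fold in both detected probe sets, with -1.24 in the dimmer one.

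Among the higher genes were Wfdc17 and Wfdc18, which encode small secreted proteins of the whey acidic protein family (2.03 and 1.46), and the membrane protein gene Emp1 (1.65, with 0.33 in its other probe set). H2-Ob, which encodes a chain of the class II modulator H2-O, was 2.66-fold higher, and Arpp21 was 2.79-fold higher. Csf1r, the receptor for macrophage colony-stimulating factor, had log2 differences of 1.40, 0.98 and 0.35 in its 3 probe sets. H3f3b (2.22), Tmem87a (1.90) and Mir1931 (1.60) were also higher. These genes, and likewise Wfdc17, Wfdc18, H2-Ob and Arpp21, each rested on a single detected probe set. The same held for the lower genes Ctse, Pik3ap1, Aldh1a1, Igkv15-103 and Igkv8-30. Of 31 genes past 2-fold that had a second detected probe set, 26 differed in the same direction in it and 14 by at least 1.5-fold. Adding the floor as an offset lowered the counts to 25 higher and 14 lower genes, and a floor at the 75th percentile to 21 and 9. The latter brought Gdpd3 to -3.39, Timp3 to -0.15, Igkv15-103 to -0.09, Nupr1 to -0.60, Cuedc1 to -0.53, Lrmda to -0.72, Eif2s3y to 0.46, Tmem87a to 0.91, Arpp21 to 0.69 and Il7r to 0.69.

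**Figure D1:**
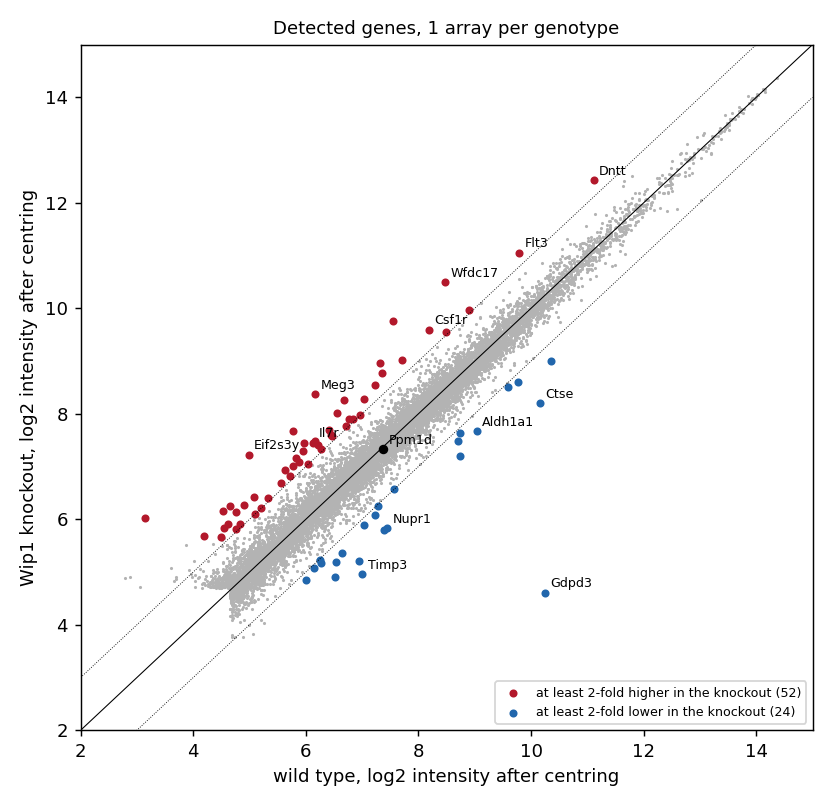
Log2 intensity after centring in the wild-type array (x axis) and the Wip1 knockout array (y axis) for 11440 detected genes; each point is 1 gene, the solid line marks equality and dotted lines 2-fold. The 52 higher genes (red) and 24 lower genes (blue) lie outside the dotted lines, with Gdpd3 farthest away and Ppm1d (black) near equality; grey points with 1 value under the floor can lie outside the lines without being counted.

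Genes of early lymphoid development were higher in the knockout. Of 16 detected members of the B cell and lymphoid progenitor list, 13 were higher and 3 lower, with 3 at least 2-fold higher. These were Dntt, the terminal transferase of lymphoid progenitors (2.49-fold, with log2 differences of 1.31, 1.40 and 1.67 in 3 probe sets), Il7r, the interleukin-7 receptor (2.51-fold, with 1.33 and at least 1.49 in 2 probe sets), and the B cell linker gene Blnk (2.20-fold, by its only probe set). The surrogate light chain genes Vpreb1 and Igll1 differed by 0.51 and 0.45. Ighm, the immunoglobulin mu heavy chain, differed by -0.97 in its brightest probe set, while its 6 detected probe sets ranged from -0.97 to at least 0.65, and Pax5 differed by 0.01. The list's median of 0.27 was above that of all 10000 matched random lists. Without the 3 genes past 2-fold the median was 0.18, still above the central 95% of random lists.

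The list of stem cell markers, which also holds the progenitor gene Flt3, was slightly higher, with members going both ways. The list's median was 0.08 over 37 detected members, above 9877 of 10000 random lists, with 23 members higher and 14 lower. Flt3, a receptor of multipotent and lymphoid-primed progenitors, was the only member past 2-fold (2112 against 892, 2.39-fold higher, by its only probe set). The stem cell transcription factor gene Hlf differed by 0.70 and Cd34 by 0.43, whereas the angiopoietin receptor gene Tek differed by -0.59 and Slamf1, which encodes the stem cell marker CD150, by -0.66 (-0.29 as the median of its probe sets). Procr (0.13), Mecom (-0.08) and Fgd5 (0.01) differed by less than the SD between probe sets. The list no longer stood apart without Flt3 (median 0.07), without probe sets of the _s_at, _x_at and _a_at classes (0.06), or against random lists not matched on intensity. A list of long-term stem cell genes, chosen after the data had been seen, had a median of 0.029, within its random range.

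Genes known to be higher in aged stem cells were lower in the knockout, as were megakaryocyte genes. The ageing list had a median of -0.21 over 29 detected members, below all 10000 random lists, with 18 members lower and 11 higher. Of these, 9 were at least 1.5-fold lower and 2 at least 1.5-fold higher. Nupr1 (-1.62) and Aldh1a1 (-1.36) were past 2-fold, followed by Sult1a1 (-0.82), Cavin2 (-0.79), Selp (-0.73), Vwf (-0.66), Slamf1 (-0.66, but -0.29 as the median of its probe sets) and Neo1 (-0.65), while Alcam (0.88) and Arap2 (0.79) went the other way. Without probe sets of the _s_at, _x_at and _a_at classes, 23 members remained and the median was -0.06, within the random range. The megakaryocyte and platelet list had a median of -0.32 over 14 members, again below all random lists, with 12 members lower. Timp3 was past 2-fold, and the platelet factor gene Pf4 (-0.77), Treml1 (-0.56, or -0.0036 with a floor at the 75th percentile), the platelet glycoprotein gene Gp5 (-0.48) and the integrin gene Itga2b (-0.44), which is also on the ageing list, were lower. Nbeal2 was higher (0.56). Because they share Itga2b, the ageing and megakaryocyte lists are not fully independent. Whether the same transcripts lie behind both shifts was not tested.

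**Figure D2:**
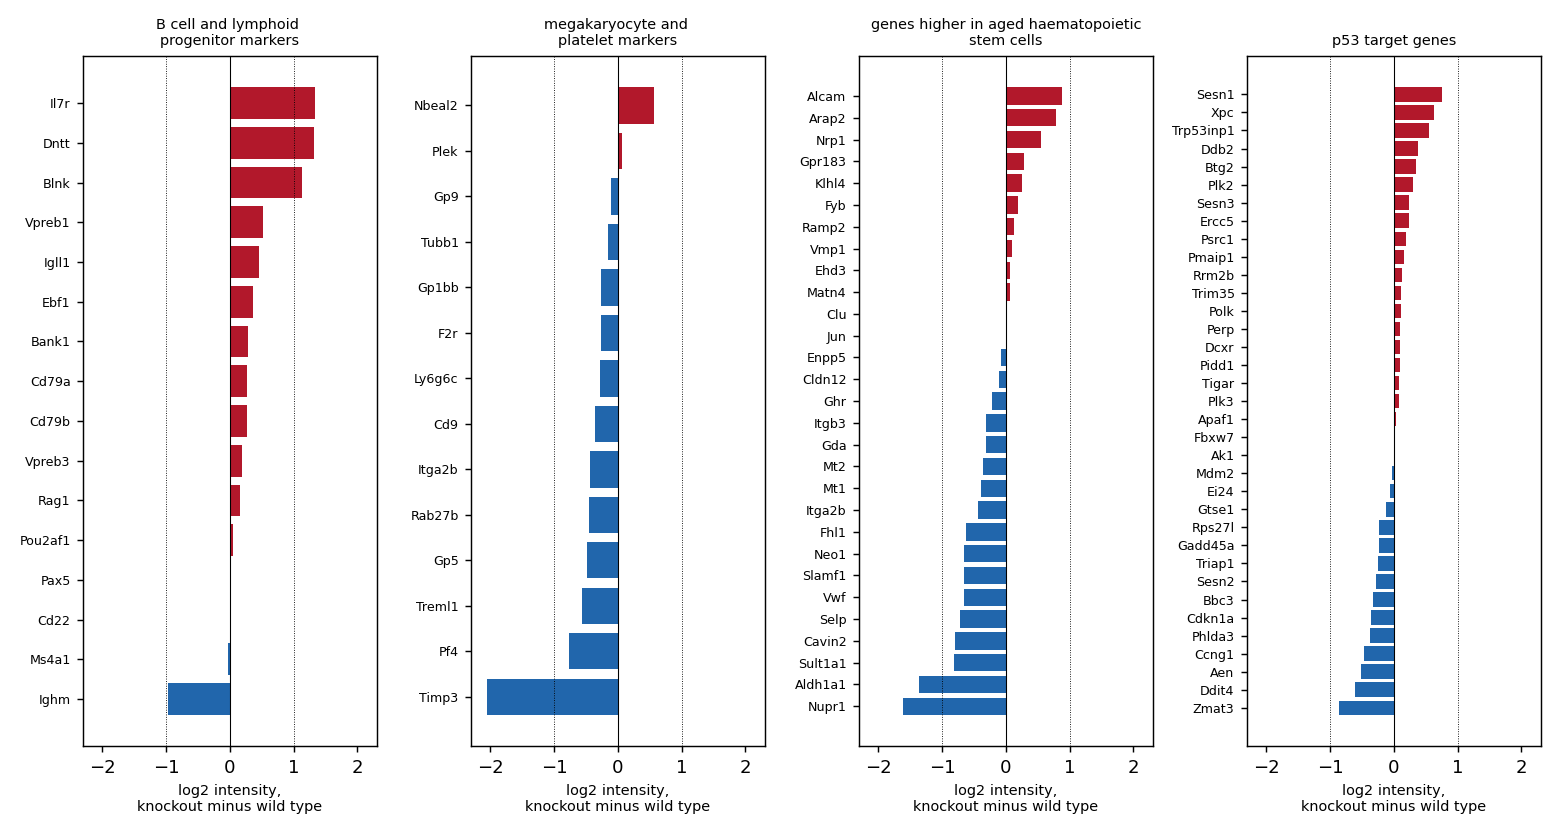
Log2 difference in intensity, knockout minus wild type (x axis), of each detected member (rows) of 4 gene lists; bars are single values from 1 array per genotype, red higher and blue lower in the knockout, and dotted lines mark 2-fold. Lymphoid genes lie mostly to the right, with Ighm at -0.97, megakaryocyte and aged stem cell genes mostly to the left, and p53 target genes on both sides of 0.

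Wip1 is known to restrain p53, and p53 target genes went both ways. Of 35 detected members 21 were higher and 14 lower, none past 2-fold, and the median of 0.08 lay within the random range (-0.09 to 0.09). Sesn1, a stress-inducible sestrin, differed by 0.76 (0.39 as the median of its probe sets), the DNA repair gene Xpc by 0.63 and Trp53inp1 by 0.56. Zmat3 (-0.85), Ddit4 (-0.61), Aen (-0.51) and Ccng1 (-0.47) were lower. The cell cycle inhibitor gene Cdkn1a was bright in both samples (2480 against 3207 in its brighter probe set), with log2 differences of -0.36 and -0.57 in its 2 probe sets, and the ubiquitin ligase gene Mdm2 differed by -0.03. The list's mean was slightly below 0, so its mean and median differed in sign. Genes of DNA damage signalling and repair had a median of -0.06 over 31 members, within the random range, and none reached 1.5-fold. The members that differed most were Xrcc6 (0.36), Ung (-0.36) and Chek1 (-0.30). After quantile normalization this list lay below the random range (-0.12). The apoptosis list lay within it (-0.01 over 25 members), with Casp12 and Cycs at -0.64 each and Casp6 at 0.50 (0.26 as the median of its probe sets).

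Components of the mTOR pathway, a growth and nutrient signalling route, did not differ as a group. Their median of 0.0041 over 31 members lay within the random range, their mean was -0.04, and none reached 1.5-fold. Rps6 (-0.48), Eif4e (-0.38) and Rraga (-0.33) were lower, and Tsc1 was higher (0.27). Without probe sets of the _s_at, _x_at and _a_at classes the median was -0.12 over 27 members, below the random range. Genes induced by mTORC1 activity were lower, with a median of -0.18 over 33 members, below all 10000 random lists, and 25 members lower against 8 higher. The lower members included Nupr1, the stress transcription factor gene Ddit3 (-1.09), the amino acid transporter gene Slc7a5 (-0.72), asparagine synthetase (Asns, -0.57) and Shmt2 (-0.50, with its other probe sets from -0.23 to -0.01), which are also known to respond to the integrated stress response. The 2 probe sets of Ddit3 differed in sign (-1.09 and 0.66). Sterol synthesis members of the same list went both ways, with Idi1 at -0.30, Fdps at -0.15, Hmgcs1 at 0.02, Sqle at 0.03 and Fdft1 at 0.48.

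Glycolysis genes had a median of -0.14 over 18 members, below 9860 random lists, with Hk2 at -0.53, Slc2a1 (-0.26 as the median of its probe sets) and Pfkp at -0.46 each and Ldha at -0.33. Slc2a1, Pfkl, Aldoa, Tpi1, Pgk1 and Ldha are also on the list of genes induced by mTORC1 activity, so these lists are not independent. The glycolysis list was within the random range with a floor at the 25th percentile, without a floor, as the median over probe sets, and without _s_at, _x_at and _a_at probe sets. Genes of the respiratory chain (-0.07), antioxidant genes (-0.07), ribosomal protein genes (-0.0017) and autophagy genes (0.02) lay within their random ranges.

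Replication genes were slightly lower in the knockout. Of 28 detected S phase genes 23 were lower, with a median of -0.15, below 9972 of 10000 random lists, and none reached 1.5-fold. Gins1 (-0.33), Cdc6 (-0.31) and the replicative helicase genes Mcm3 (-0.26) and Mcm4 (-0.25) were lower, and Orc1 was higher in its brightest probe set (0.45) but not in the median of its probe sets (-0.09). The G2 and M phase list was within the random range (-0.07 over 29 members), with the proliferation marker gene Mki67 at -0.12, Nuf2 at -0.28, Aurkb at -0.27 and Kif23 at 0.28. Inhibitors of cyclin-dependent kinases and quiescence genes had a median of -0.0072, with Txnip at 0.39, Rb1 at -0.35 and Cdkn2c at -0.29.

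Markers of other blood cells were compared because a sorted sample can hold them. The list of monocyte, macrophage and dendritic cell markers had a median of 0.05 over 20 members, within the random range, with members going both ways. The class II genes H2-Eb1 (-1.11), H2-Aa (-0.92) and H2-Ab1 (-0.91) were lower, while Csf1r, the complement gene C1qc (at least 0.85) and the transcription factor gene Irf8 (0.77) were higher. Without probe sets of the _s_at, _x_at and _a_at classes this list lay above the random range (0.15). Neutrophil granule genes had a median of -0.08, with Ms4a3 at -0.72, the integrin gene Itgam at 0.62 and myeloperoxidase (Mpo) at -0.57. Erythroid markers had a median of -0.03, with 9 members higher and 9 lower. The transcription factor gene Gata1 (-0.84, or -0.21 with a floor at the 75th percentile), Aqp1 (-0.76) and Icam4 (-0.59) were lower, and the band 3 gene Slc4a1 (0.49) and Mgst3 (0.43) were higher. The list also named globin genes, abundant in red cells, but probe sets assigned to several globin genes were kept out of the gene comparison and of this median. Those probe sets were higher in the knockout, with log2 differences of 2.18, 2.29 and at least 0.82 for alpha globin and 1.16 for beta globin. T and natural killer cell markers (-0.09), mast cell markers (0.10), stromal markers (-0.0065) and genes of non-blood tissues (-0.05) lay within their ranges. With a floor at the 75th percentile the stromal list lay above its range (0.47), with 2 members left.

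Immediate early and heat shock genes had a median of 0.15 over 30 members, above all 10000 random lists, with 19 higher and 11 lower. The transcription factor genes Nr4a2 (0.77, or 0.41 as the median of its probe sets), Klf2 (0.75) and Klf4 (0.68) and the phosphatase gene Dusp2 (0.71) were higher, whereas the heat shock genes Hsph1 (-0.48) and Hsp90aa1 (-0.30) were lower. Inflammatory genes had a median of 0.09 over 23 members, just above the random range, with Socs3 at 0.58 (0.94 without _s_at, _x_at and _a_at probe sets) and Bcl3 at -0.78 (0.0037 with a floor at the 75th percentile). That list returned within the range after quantile normalization, at each other floor, without probe sets of the _s_at, _x_at and _a_at classes, and against unmatched random lists. Interferon-response genes lay within it (0.03 over 30 members), with Ifi27l2a 2.09-fold higher and Cxcl10 at -0.73.

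**Figure D3:**
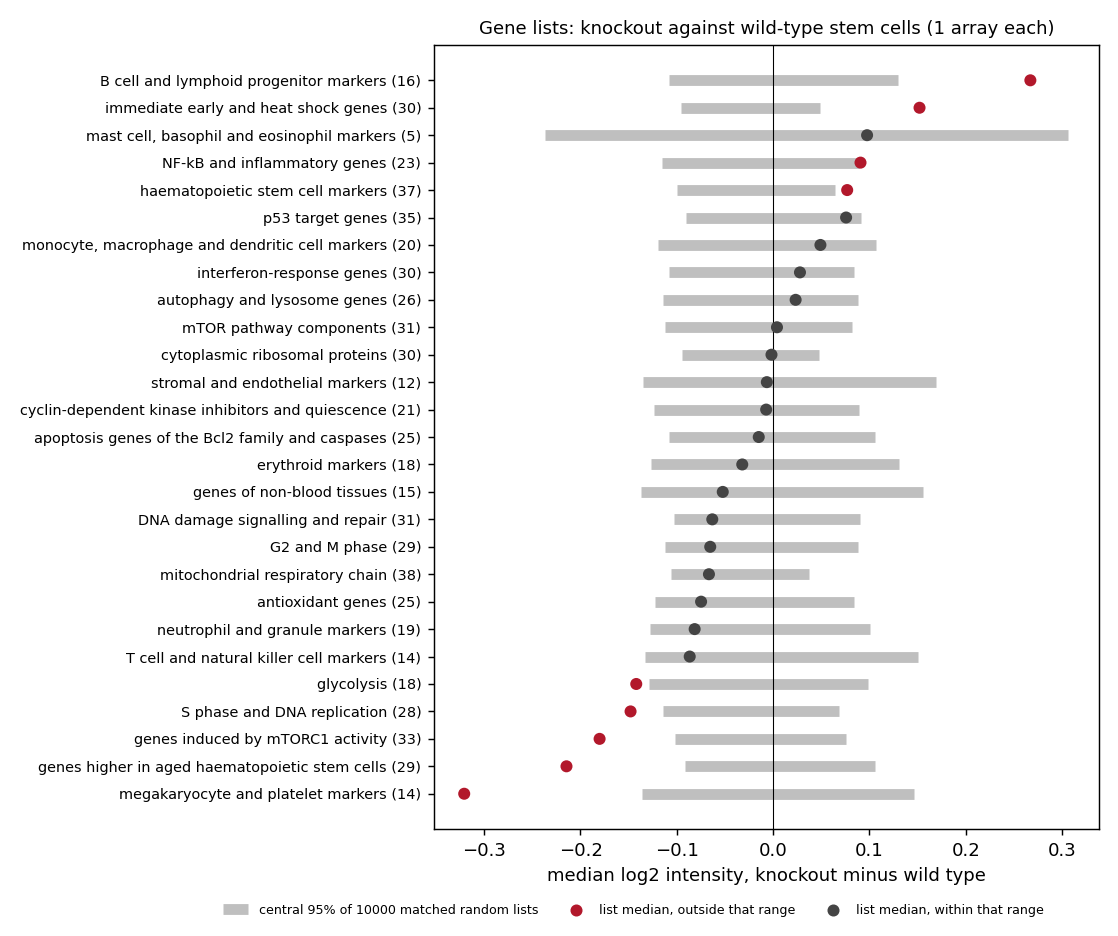
Median log2 difference in intensity, knockout minus wild type (x axis), for 27 gene lists (rows, with the number of detected members in brackets); grey bars give the central 95% of 10000 matched random lists, and red medians lie outside it. Megakaryocyte and aged stem cell genes lie lowest (-0.32 and -0.21) and lymphoid genes highest (0.27); the sex-linked list (0.81 over 4 members) is not drawn.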

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

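The tests of symmetric noise and the interval of the intronic RNA test were chosen after the values had been seen; the tests of scaling and of intronic RNA were not.

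Probe sets with no listed gene, which the gene comparison left out, were mostly higher in the knockout where they differed. Among 3406 detected probe sets with several genes or none, 77 were at least 2-fold higher and 4 at least 2-fold lower: 73 and 1 of those with no listed gene, but 4 and 3 of those with several genes, where no such skew is seen. Symmetric noise would give about as many lower as higher, but 95.1% of both kinds together were higher. That share is the count that raised the question, so it speaks only against noise that is symmetric and independent between probe sets. After loess on the mean 92.2% still were higher, which argues against scaling that depends on intensity as the whole cause. Noise shared by the probe sets of 1 array was not tested. More intronic or unspliced RNA in the knockout sample is a candidate explanation: among 69 dimmer probe sets of named genes past 2-fold, 78.3% were higher, over the bound of 75% set beforehand, but the exact 95% interval of 66.7 to 87.3 reaches below that bound and holds the 68.4% found among the brightest probe sets. That interval treats the probe sets as independent, though some belong to the same gene, and it holds no variation between samples. Whether the dimmer probe sets measure introns is not known here, so their share cannot single out intronic RNA. Over all 8466 detected dimmer probe sets of named genes the median was 0.01, against 0.10 over 2816 with no listed gene. Genomic DNA in the sample and RNA quality were not tested, and no biological explanation was tested.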

How the results depend on the processing

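All settings but one were chosen before the data were examined. The counts of genes past 2-fold (52 higher, 24 lower) stayed within 1.5 times under no centring, quantile normalization, loess, centring on all probe sets, a floor at the 25th percentile, no floor, the median over probe sets, and without _s_at, _x_at and _a_at probe sets. No centring and centring on all probe sets were in effect the same setting, with 49 higher and 26 lower genes in each. Both differed from the main setting only by a shift of -0.01, so they could hardly move any result. They were 25 and 14 with the floor added as an offset and 21 and 9 with a floor at the 75th percentile, which by construction shrink differences of dim genes, 263 and 177 at 1.5-fold, and 8 and 7 at 3-fold. Pearson's r was 0.992 with a floor at the 25th percentile, 0.994 without a floor and 0.979 with a floor at the 75th. Without _s_at, _x_at and _a_at probe sets the stem cell list (0.061) and the aged stem cell list (-0.063) no longer stood apart and the mTOR component list did (-0.12); fewer members were measured, and the cause was not otherwise tested. The stem cell list also lost its place against unmatched random lists (median 0.077) and without Flt3 (0.065, a setting chosen after seeing the data). The sex-linked list turned to -0.11 with a floor at the 75th percentile and to -0.24 without its members past 2-fold, with 2 members left in each. The lymphoid, megakaryocyte, mTORC1-induced and S phase lists stood apart under each setting run for them. Ppm1d and the median of its neighbours moved by less than the SD between probe sets in each, and Ppm1d was 0.02 as the median of its probe sets. Of 956 values of 99 named genes, 58 moved by more than that SD. The 956 include the values under no centring and under centring on all probe sets, which could hardly move. No paired analysis was possible because each group has 1 sample. Signal over background limits genes near the floor.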

Other observations

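The gene lists in this part, and the tests of mature B cells, of male cells and of the chromosome segment, were chosen after the data had been seen. For the tests of progenitors, scaling, probe variants, homologues and imprinted genes, the rule was set before the result was seen. Any gene list made for those tests was still chosen after the data had been seen.

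Genes of lymphoid-primed progenitors had a median of 0.70 over 17 detected members, above all 10000 matched random lists, with 9 at least 1.5-fold higher. Beside Flt3, Dntt, Il7r and Blnk these included the chemokine receptor gene Ccr9 (at least 1.60, but at least 0.48 in its other detected probe set), the chromatin organiser gene Satb1 (1.00), Notch1 (0.90), Il12a (0.86) and Ets1 (0.70, with its other probe sets from -0.12 to 0.91). The integrated stress response list was lower (-0.28 over 20 members), with 16 members lower. Both lists were built around genes already seen to differ and are not independent evidence of their direction. Among imprinted genes the noncoding RNA Meg3 was 4.62-fold higher, at 329 against 71.9, with detected probe sets from 2.58 to a bound of -0.04, Igf2r differed by 0.92 and Grb10 by -0.69. The imprinted list as a whole (0.10 over 15 members) lay at the 91.69th percentile of random lists, within their range.

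The Y-linked genes had a median of at least 1.38 and the Xist probe sets one of -0.71, which a larger share of male cells in the knockout sample would give, while their X-linked homologues (median -0.17 over 4 genes) were not higher, which argues against cross-hybridisation to them.

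Lymphoid progenitor genes were higher while megakaryocyte and aged stem cell genes were lower. Scaling with intensity as the whole cause is argued against, since the lymphoid list lay above all 10000 random lists matched on mean intensity. Its median of 0.25 after loess adds little, because the matching already accounts for most of a trend with mean intensity. RNA of mature B cells in the knockout sample would raise their abundant transcripts, but these genes had a median of -0.54, with 10 of 12 detected members lower. Jchain was at -1.17 and Ighm at -0.97 and -0.88 in its brightest probe sets, whereas Cd79a and Cd79b differed by 0.27 each. The list was made after class II genes and Ighm had been seen to be lower, so its median does not decide this explanation. A larger share of lymphoid-primed progenitors among the sorted knockout cells may contribute, but the test leaves this open. Genes of multipotent progenitors had a median of 0.33, above all random lists, but genes of long-term stem cells had one of 0.029, within the range. Both lists were chosen after the data had been seen and are not independent evidence. A different share of male cells stays open too, because the Y-linked genes differed by a median of at least 1.38 and no comparison within one sex can be made. An effect of the missing phosphatase on the stem cells remains untested, as each genotype had 1 array.

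Genes that flank Ppm1d on chromosome 11 (gene order of assembly GRCm38.p6) differed by at least 1.5-fold more often than matched genes: 10 of 83 detected neighbours within 5 Mb did, against at most 7 in the central 95% of random sets, and 14 of 10000 sets reached as many. By their brightest probe sets these were Wfdc17, Wfdc18, Slfn8, Slfn5, Ccl9 and Mir142, which were higher, and Cuedc1, Dhx40, Ccl5 and Zfp830 (-0.66), which were lower, with a median of 0.03 over all neighbours. In other detected probe sets Zfp830 differed by 0.01 and 0.09, Cuedc1 by -0.40 and a bound of -0.13, Slfn5 by 0.46 and Ccl9 by 0.32. A flanking segment of another strain, kept since the gene was targeted, is a candidate explanation, but this count is the pattern itself, and neighbours of one gene family can vary together, which random sets do not mimic. Sequence variants under single probe sets stay open: of 6 other detected probe sets of these genes, 33.3% differed in the same direction by over 0.5 times as much, too few to decide. An effect of genotype on these genes was not tested.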
